A study of Mus musculus with 8 samples.

How the data were processed

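Zmat3-bound RNA was profiled by crosslinking and immunoprecipitation (CLIP) in mouse embryonic fibroblasts transformed with E1A and oncogenic Hras. Per the labels, 3 control lines carried different negative-control guide RNAs, and 1 line came from Zmat3 knockout fibroblasts. Per the labels, cells were UV-crosslinked, the lysate was treated with RNase and immunoprecipitated with an anti-Zmat3 antibody, and RNA from the 35 to 110 kDa part of the gel was sequenced. The series holds 8 samples, namely 4 immunoprecipitates (IP) and the 4 matching inputs.

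The deposited data were 7 peak lists on mm10, the build named in the submitters' processing notes. Of these lists, 4 compared an IP with input (controls 1 to 3 and the knockout), and 3 compared a control IP with the knockout IP. Inputs had no list of their own. Each peak had a position, a strand, a −log10 p-value and a log2 fold, both computed by the authors for the IP against the named comparator. These units were read from the values and the layout, because the lists have no header. The −log10 p-value deposited by the authors was capped at 400, and it was 0 at every peak with a log2 fold below 0. The aligner, the peak caller, the handling of PCR duplicates, the choice of input library and the treatment of peaks without reads in the comparator are not given in the sources used here. The largest log2 folds over the knockout IP may therefore depend on how the authors treated peaks without knockout reads. The lists contain no read counts, so the depth of each library is unknown and no counting interval was computed.

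A peak was called enriched at a log2 fold of at least 3 and a −log10 p-value of at least 3. A control peak qualified if it was enriched over input and overlapped, by at least 1 nt on the same strand, a peak of the same control enriched over the knockout IP. Overlapping qualifying peaks of different controls were merged, and a region counted as reproducible if at least 2 of the 3 controls supported it. Within a region, the value of a library is that of its peak with the highest log2 fold, and region values are given as mean and standard deviation (SD) over controls. The number of regions expected by chance came from 100 circular shifts of the qualifying peaks among the called peaks of each library. A stricter null, added after the data were seen, permuted the qualifying peaks 100 times among the called peaks of the same gene. Coordinates are 1-based.

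Genes were assigned from the RefSeq gene table of the same build, which gives gene spans without strand or exons. A peak that overlapped a non-coding gene of at most 500 nt was assigned to it as a small RNA; all other peaks were assigned by their midpoint to a protein-coding gene, then to a long non-coding RNA, then to another gene. Peaks in the span of several genes were not named. A genome sequence and an exon annotation were not used here, so 5 of the 10 planned results were not analysed here. These were the intron share of the regions, their distance to 3′ splice sites, their uridine content, their 5-mers, and the intron share in control against knockout. The last was replaced by the share of peaks per gene class, an alternative added after the data were seen.

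The 12 gene lists were fixed before the data were examined, as were the thresholds and the rule for named genes. The background of the list test was the 8680 genes with called peaks in all 3 controls. The number of list members with a reproducible region was set against 10000 random gene sets matched on deciles of called peaks (two-sided permutation test, Benjamini-Hochberg adjustment over the lists). Named genes were Zmat3, Mdm2, Mdm4, Cdkn1a, Trp53, Cd44 and Ptbp1 whatever their values, and the 20 genes whose best region, supported by all 3 controls, had the highest minimum log2 fold over the knockout IP. Further names were the genes with most regions supported by all 3 controls, up to 4 members per list with a region, and the 5 genes with the highest log2 fold among enriched knockout peaks. The rule allowed 5 genes with most regions, and Mdm4 was the one gene with more than 1 such region. Genes named outside this rule are said to be so where they appear.

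The knockout had 1 library, so control and knockout counts are given side by side. The smallest p an exact permutation test of 1 against 3 libraries can give is 0.25. Alternatives were other thresholds on the log2 fold and the p-value, other overlap criteria, support by all 3 controls, enrichment over 1 comparator alone, other list tests, and leaving out each control. Region calling was tested on simulated data with the 129323 called positions of control 1 and those of the other controls. Of 50 regions planted in 3 libraries at a log2 fold of 4, 50 were recovered, as were 50 of 50 at a log2 fold of 6. At a log2 fold of 2, and for regions planted in 1 library, 0 of 50 were recovered. The planted values were written directly onto called peaks, so these outcomes follow from the thresholds and the support rule. They check the procedure and do not measure its sensitivity to reads or depth. The list test, tested on simulated hits among 8680 genes, detected a planted core spliceosome list with 10 of 49 members hit in 50 of 50 runs and gave 0 false calls in 600 list tests. The planted count was above that of any real list, at most 5 members. Power for excesses of the size seen here was therefore not measured. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.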

Results

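The data comprised CLIP peak lists for the RNA-binding zinc finger protein Zmat3 from 3 control lines and 1 Zmat3 knockout line of transformed mouse embryonic fibroblasts. The lists over input held 129323, 153768 and 122284 called peaks in controls 1 to 3 and 167648 in the knockout. Read depth was unknown, because the lists give no counts. The series set out to identify RNAs bound by Zmat3, and the knockout IP measures what the antibody recovers without the protein.

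Within Zmat3 itself (chromosome 3, 32334792–32365665), 42, 48 and 39 peaks were called over input in controls 1 to 3, and 38 in the knockout. Zmat3 RNA was therefore still sampled in the knockout line, and these peaks do not measure the protein. Against the knockout IP, 4, 16 and 1 of the Zmat3 peaks were enriched in controls 1 to 3, whereas over input 0, 1 and 0 were enriched, and 0 in the knockout. A Zmat3 region at 32343551–32343733 on the minus strand had a log2 fold over the knockout IP of 4.18 ± 0.13 (SD, n = 3) but a log2 fold over input of 0.88 ± 0.53 (SD, n = 3), and it did not count among the reproducible regions.

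The first comparison asked how much RNA was enriched over input with and without Zmat3. Enriched peaks numbered 1319, 1622 and 604 in controls 1 to 3, a mean of 1182 ± 523 (SD, n = 3), against 529 in the knockout. The control mean was 2.23 times the knockout count, although control 3 lay close to the knockout. As a share of called peaks, 0.856% ± 0.314 (SD, n = 3) were enriched in the controls and 0.316% in the knockout. The genes with the highest knockout values were Frmd8 (log2 fold over input 6.40), Ubtd1 (6.11), Smyd3 (5.77), Dcakd (5.76) and Atxn2 (5.71). Each of these knockout peaks also overlapped a control peak above its input in all 3 controls, with log2 folds of 4.43 to 5.40 for Frmd8 and 5.44 to 5.85 for Dcakd. For Smyd3 they were 3.95, 2.74 and 3.44 in controls 1 to 3, so that control 2 lay under the threshold. With 1 knockout library against 3 controls, an exact permutation test across libraries could not reach a p below 0.25.

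**Figure D1:**
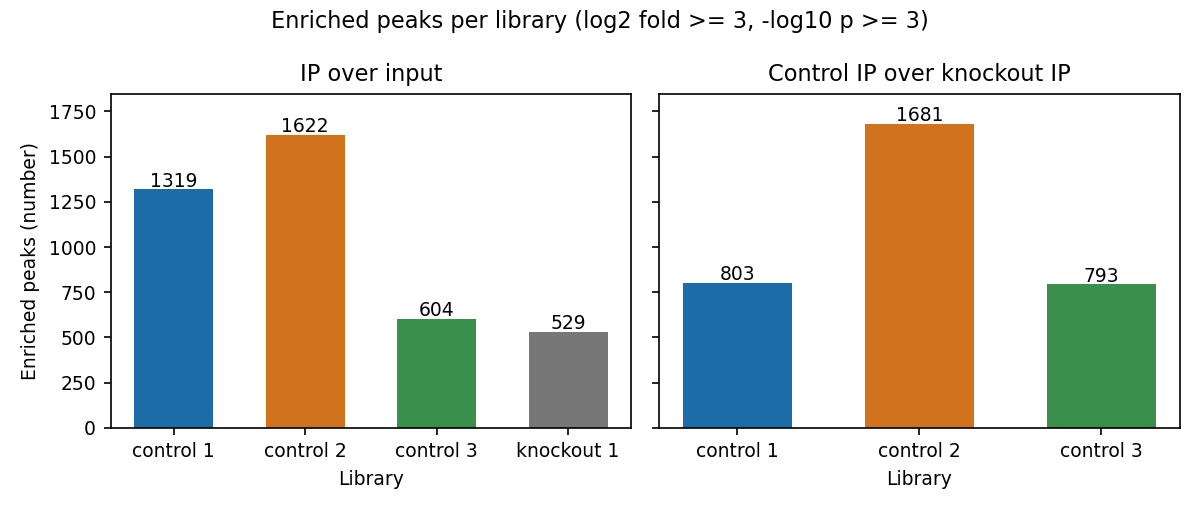
Number of enriched peaks per library (bars, 1 library each) for the IP over input on the left and for the control IP over the knockout IP on the right. Over input, the controls reached 1319, 1622 and 604 peaks and the knockout 529; over the knockout IP, the controls reached 803, 1681 and 793.

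Small RNA genes took a larger part of the enriched peaks in the knockout. They held 6.81% of enriched knockout peaks, above all 3 controls, which ranged from 0.758% to 2.32% with a mean of 1.52% ± 0.781 (SD, n = 3). Long non-coding RNAs held 3.78% in the knockout against 1.06% ± 0.329 (SD, n = 3), and protein-coding genes 88.1% against 96.3% ± 0.985 (SD, n = 3). Among all called peaks, the share of small RNA genes was 0.557% in the knockout and 0.727% ± 0.0183 (SD, n = 3) in the controls.

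Part of the over-input enrichment was shared with the knockout. An enriched knockout peak overlapped 16.6%, 10.5% and 33.9% of the enriched peaks of controls 1 to 3, a mean of 20.3% ± 12.2 (SD, n = 3). Between pairs of controls the share was 39.1% on average, from 23.4% to 60.8% over 6 comparisons. The share depends on the size of the partner list, and the knockout list was the smallest, with 529 enriched peaks. With control 3 as partner (604 enriched peaks), it was 28.8% for control 1 and 23.4% for control 2.

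The direct comparison of IPs asked which peaks depended on Zmat3. Against the knockout IP, 803, 1681 and 793 peaks were enriched in controls 1 to 3, a mean of 1092 ± 509.8 (SD, n = 3). The overlap of these peaks between controls was 39.1% on average (22.8% to 58.9%), against 0.649% after circular shifts. Among positions called in both controls of a pair, 353, 318 and 494 were enriched in both, where independent lists would share 15.3, 9.54 and 20.8. All 3 lists share the 1 knockout library, and part of this excess may come from it. Unchanged groups could not be simulated without read counts. Over-knockout peaks of one control overlapped over-input peaks of another, which share no library, at 23.3% on average (10.8% to 44.6%), against 0.675% after shifts.

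Requiring both comparisons in at least 2 controls gave 203 regions in 193 genes, led by Fnbp4, Agtrap, Rcc1, Gnpat and Pck2 and including 2 regions in Mdm4. Of the regions, 77 were supported by all 3 controls and 126 by 2. Protein-coding genes held 202 of them, and the remaining region lay in the microRNA gene Mir7031, named here outside the rule for named genes. The median length was 114 nt. A called knockout peak overlapped 9 of the 203 regions and an enriched one overlapped 0. The required enrichment over the knockout IP favours such a low overlap, so it is not independent evidence. At these 9 regions the median log2 fold over input was 0.23 in the knockout, against a median control mean of 3.51; the selection of the regions for enrichment in the controls and over the knockout IP favours this order. Circular shifts gave 1.08 regions on average and at most 4. Permutation within genes gave 21.8 on average and at most 32, and 0 of 100 draws reached 203. Both nulls moved the peaks of each control independently, although all 3 controls were compared with the same knockout library. Part of the excess over these numbers may come from that library. Control 2 supported 199 of the regions and control 1 supported 153. The count was 81 without control 2 and 129 without control 1.

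Fnbp4, which encodes a formin-binding protein, had the highest minimum over the 3 controls. Its region on the plus strand of chromosome 2 at 90768262–90768472 reached a log2 fold of 6.90 ± 0.37 over the knockout IP and 6.42 ± 0.34 over input (SD, n = 3). Agtrap, encoding an angiotensin receptor-associated protein, followed at 6.66 ± 0.51 over the knockout IP (SD, n = 3; chromosome 4, 148084001–148084067). Rcc1, the exchange factor of the GTPase Ran, had 6.30 ± 0.28 (SD, n = 3), and Gnpat, an enzyme of ether lipid synthesis, had 6.08 ± 0.11 (SD, n = 3). Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, had 6.17 ± 0.41 over the knockout IP and 6.65 ± 0.71 over input (SD, n = 3). Other called Pck2 peaks also lay above the median of all called peaks over the knockout IP, by 1.28, 1.38 and 1.28 in controls 1 to 3. Upf3b, a factor of nonsense-mediated decay, had 6.16 ± 0.37 (SD, n = 3; chromosome X, 37092699–37092804). Cltc, the clathrin heavy chain, had 6.39 ± 1.00 (SD, n = 3; chromosome 11, 86695730–86695843) and was the gene with most regions, 3 in all. The vascular growth factor gene Vegfa had 5.80 ± 0.42 (SD, n = 3), with its region at 46018942–46019058 on the minus strand of chromosome 17. The leading 20 also included Dcaf8, Afdn, Pofut1, C2cd5, Rpl10, Cactin, Ilkap, Limk2, Pogz and Inf2, besides Mdm4. The means of these 10 genes other than Mdm4 over the knockout IP lay between 5.57 for Ilkap and 6.07 for Dcaf8.

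**Figure D2:**
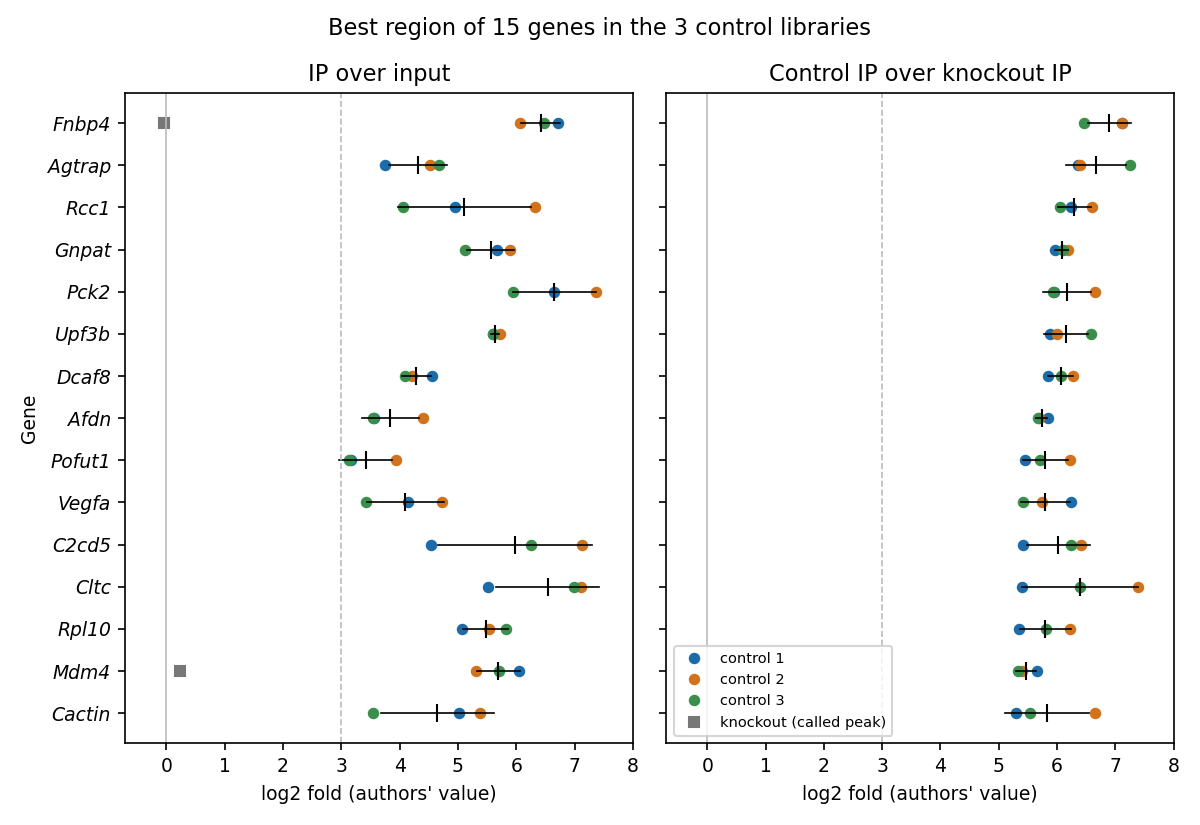
Log2 fold over input (left) and over the knockout IP (right) of the best region of the 15 leading genes. Points are the 3 control libraries, vertical ticks their mean, horizontal lines the SD, grey squares called knockout peaks over input, and dashed lines the threshold of 3. Fnbp4 reached 6.90 ± 0.37 over the knockout IP, and its knockout peak lay at −0.031 over input.

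Mdm4, which encodes an inhibitor of p53, was the one gene with 2 regions supported by all 3 controls. The stronger region spanned 133004395–133004631 on the minus strand of chromosome 1, inside the Mdm4 span of 132986105–133030587, with a log2 fold of 5.69 ± 0.37 over input and 5.46 ± 0.18 over the knockout IP (SD, n = 3). The knockout peak called there had a log2 fold of 0.23 over its input. The other region, at 133003891–133004032, reached 3.33 ± 0.45 over input and 4.51 ± 0.24 over the knockout IP (SD, n = 3), with the knockout at −0.67. Whether these regions lie in exons or introns was not analysed here.

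**Figure D3:**
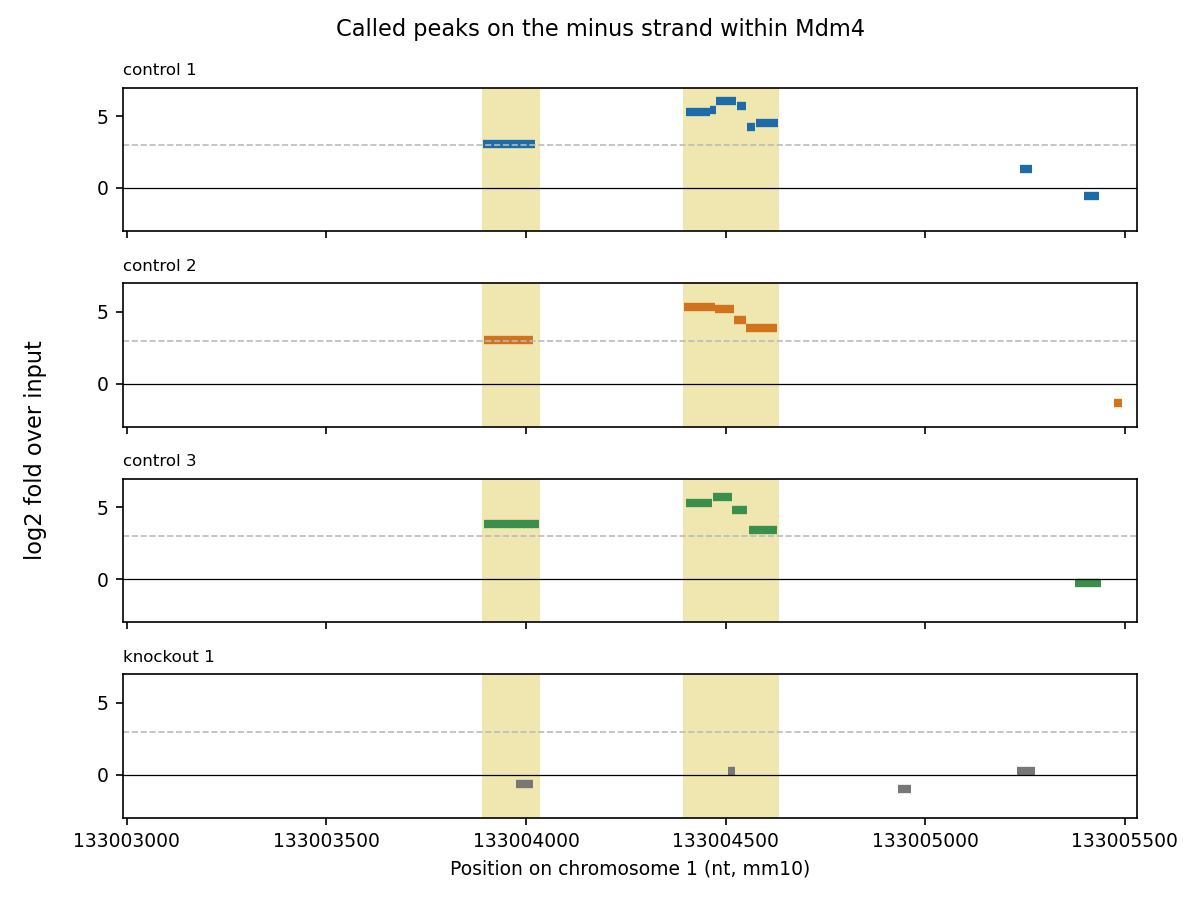
Called peaks on the minus strand around the 2 Mdm4 regions (shaded), by library, with position on chromosome 1 on the horizontal axis and log2 fold over input on the vertical axis. The dashed line is the threshold of 3. The control peaks in the shaded regions lie above the threshold, and the knockout peaks there lie at 0.23 and −0.67.

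Among other genes of the p53 pathway, Mdm2, the ubiquitin ligase of p53, had a qualifying peak in control 2 alone, at 117705240–117705350 on the minus strand of chromosome 10, with log2 folds of 4.67 over input and 4.59 over the knockout IP. The overlapping peak of control 3 had 4.57 over input but 0.73 over the knockout IP, and in control 1 none of the 24 called Mdm2 peaks was enriched over input. The knockout had 1 enriched Mdm2 peak over its input. In Cd44, a cell surface receptor, 2, 0 and 1 peaks of controls 1 to 3 were enriched over input. Over the knockout IP 0 were enriched in each control, and the knockout had 1 enriched peak over its input. Overlapping peaks of controls 1 to 3, starting at 102829377 to 102829379 on chromosome 2, had 3.26, 2.43 and 3.64 over input. Those of controls 1 and 3 had 1.41 and 1.04 over the knockout IP. The enriched knockout peak lay at another site, 102811567–102811613 (3.60 over input). The p53 target Cdkn1a, the p53 gene Trp53 and the splicing repressor gene Ptbp1 had 0 enriched peaks in every list.

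Regions lay in members of most of the fixed gene lists, and no list passed the test after adjustment. SR proteins and hnRNPs held a region in 5 of 48 background genes, where 1.58 were expected. Sfpq had a log2 fold of 5.61 ± 0.60 over the knockout IP, Hnrnpk 3.97 ± 0.83, Srsf5 3.61 ± 0.95 and Hnrnpab 3.96 ± 0.68 (SD, n = 3). The matched permutation test gave p = 0.0400 and, adjusted over the 12 lists, 0.240. The count was 3, 1 and 3 without controls 1, 2 and 3, with unadjusted permutation p of 0.150, 0.964 and 0.244. Ribosomal protein genes held a region in 3 of 56, with 0.429 expected (permutation p = 0.0194, adjusted 0.233). Their count was 3, 2 and 2 without controls 1, 2 and 3, with unadjusted permutation p of 0.00540, 0.0202 and 0.0690. Adjusted over the lists, these p were 0.0648, 0.121 and 0.414. The 3 genes were Rpl10 with 5.80 ± 0.44, Rpl32 with 4.71 ± 0.58 and Rpl29 with 3.90 ± 0.45 (SD, n = 3). The core spliceosome list had 4 of 49, with 1.56 expected (permutation p = 0.141, adjusted 0.344), namely Prpf8 with 4.24 ± 0.26, Rbm25 with 4.14 ± 0.91, Sf3b3 with 3.81 ± 0.65 and Eftud2 with 3.80 ± 0.34 (SD, n = 3). All 4 had a region supported by all 3 controls, so leaving out 1 control could not remove them. Without control 1, 2 or 3 the expected number fell to 1.01, 0.676 and 1.20. The unadjusted permutation p were then 0.0358, 0.00740 and 0.0604 (adjusted 0.215, 0.0888 and 0.414) and do not measure stability. Among regulators of p53, Mdm4, Crebbp and Atm held a region, 3 of 25 with 0.903 expected (permutation p = 0.115, adjusted 0.344; 1 of 25 without control 2). Crebbp had 4.95 ± 0.06 (SD, n = 3). Atm had 3.53 ± 0.32 over the 2 controls with a called peak. In this permutation test 0 of the 12 lists passed an adjusted p of 0.05, and 2 passed it unadjusted.

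Of the p53 target genes, 1 of 29 held a region, Btg2 (3.42 ± 1.10 over the knockout IP, SD, n = 3), with 0.670 expected. The signalling kinase genes Map4k4 (5.62 ± 0.95) and Map2k5 (4.69 ± 0.90; SD, n = 3) also held a region. Chromatin regulators had 3 of 64 with 3.76 expected, namely Nsd2 (3.68 ± 1.15), Dnmt1 (3.20 ± 0.55) and Kdm6b (3.07 ± 0.17; SD, n = 3). RNA decay factors had 2 of 49 with 1.92 expected, Upf3b and Cnot1 (4.61 ± 0.27, SD, n = 3). DNA repair and replication had 1 of 59 with 1.76 expected, Rif1 (4.29 ± 0.57, SD, n = 3). No region lay in the 31 genes of cell adhesion and extracellular matrix, where 1.60 were expected, or in the 50 genes of actin cytoskeleton and focal adhesion, where 2.52 were expected. Markers of other cell types were represented by 3 background genes, with 0 regions. The adjusted permutation p of these lists lay between 0.344 and 1. The regions of Sfpq, Hnrnpk, Srsf5, Rpl29, Crebbp, Atm, Btg2, Nsd2, Dnmt1, Kdm6b and Cnot1 rested on 2 controls, and each was lost when 1 of these was left out.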

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

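The tests on genes with 1 region, on genes with 2 or more regions and on chromosome Y were chosen only after the values had been seen. In the second Mdm4 region (chromosome 1, 133003891–133004032), the called knockout peak had a log2 fold over input of −0.67, while the controls had 3.33 ± 0.45 (SD, n = 3). In the Fnbp4 region the knockout peak had −0.031, against 6.42 ± 0.34 in the controls (SD, n = 3). Both are listed because the knockout value lay below 0 where all 3 control values lay above 0. The regions had been selected for high control values and for enrichment over the knockout IP, which favours such a contrast, and the Fnbp4 knockout value is close to 0. The difference was not tested, since the knockout had 1 library.

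Besides the 203 regions enriched over both comparators, 191 were enriched over the knockout IP in 2 or more controls with no enrichment over input. Here no enrichment means that the thresholds over input were not met, and some of these regions lay above input. A higher level of the RNA itself in the control lines was weighed against binding by Zmat3. As a median over genes, the other called peaks of the same genes lay at most 0.25 (log2) above the median of all called peaks in any of the 3 controls. For the genes of the 203 regions the value was at most 0.12. Peaks within the regions were left out first, which can lower these values. The remaining peaks were thus raised little in either set as a whole. A higher RNA level is not excluded by this for either set, nor for single genes such as Pck2 (1.28, 1.38 and 1.28). Genes with 1 such region gave a median of at most 0.22. The 18 genes with 2 or more regions gave medians of 0.95, 0.26 and 1.06 in controls 1 to 3. A higher RNA level stays open for them as well. On chromosome Y the called peaks outside the regions lay 1.25, 1.74 and 2.02 above the median, but the 95% interval of control 1, from 9 peaks, reached down to 0.49, and RNA level and binding cannot be told apart there. Loss of Zmat3, the biological difference of the design, stays open for all of these, as does a difference in strain or sex between the lines, which is not given in the sources used here, and a change in part of an RNA was not tested: in Zmat3 itself the other peaks lay 1.22, −0.88 and −0.026 from the median, and all called peaks 1.42, 0.89 and 0.91 above it.

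Of the 806 regions that qualified in 1 control, 737 came from control 2. Where controls 1 and 3 had a called peak in these regions, its log2 fold over input lay 1.54 and 1.58 above the library median. Peaks overlapping any called peak of control 2 lay at −0.26 and −0.42. Lower sensitivity of controls 1 and 3 may thus account for part of the regions. Over input, however, control 1 had 1319 enriched peaks (1.02% of called peaks), against 1622 (1.05%) in control 2 and 604 (0.494%) in control 3. These counts give little sign of lower sensitivity in control 1. A called knockout peak overlapped 61.5% of the enriched peaks of control 1 and 63.9% of control 3, against 25.4% of control 2. Clusters that were not called at all are a further candidate explanation. Of the 737 regions, 58.9% overlapped a called peak in both control 1 and control 3, and 87.8% in at least 1 of these. This lies between the bounds set beforehand, so this part cannot be told apart. No biological explanation was tested, as the labels separate the control lines by their negative-control guide RNA alone.

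Small RNA genes held more of the enriched peaks in the knockout than in any control, and recovery of structured RNAs without Zmat3 was weighed as the explanation. It needs small RNA genes to be at least 2 times as frequent among enriched control peaks that overlap an enriched knockout peak as among the others. The shares were 6.47% against 0.895% in control 2 and 4.39% against 1.25% in control 3, but 0.457% against 0.818% in control 1, where 1 of 219 peaks was a small RNA. With so few peaks the explanation cannot be told apart from a difference between single libraries, and loss of Zmat3 stays open, untested.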

How the results depend on the processing

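The alternatives added after seeing the data were the null within genes, the merging of peaks 1 nt apart, the gene classes and the overlap without a shared library. No paired analysis was possible because the inputs have no peak list and the knockout has 1 library. The control-to-knockout ratio of enriched peaks stayed above 1 in all settings run, from 1.82 to 2.78. At a log2 fold of at least 1, 2405 peaks were enriched over the knockout IP and 1905 over input (control means), 1012 in the knockout, and 386 regions were found. At a log2 fold of at least 2 the counts were 1713 over the knockout IP, 841 in the knockout and 308 regions. At a −log10 p-value of at least 5 they were 506 and 625 (control means), 302 in the knockout and 102 regions, and at 8 they were 233, 309.7, 162 and 43. Support by all 3 controls gave 77 regions, enrichment over input alone 561 and over the knockout IP alone 598; leaving out each control gave 81 to 150. Counts fall under stricter criteria by construction. Of the 20 leading genes, 20 kept a region at a −log10 p-value of 5 and 15 at 8; looser criteria and left-out controls could not remove them, since all 3 controls support their regions. Without controls 1, 2 or 3, 5, 11 and 6 of the 40 named genes with a region lost it. Of 498 recomputed named gene values, 19 moved by more than the SD, 10 of these downwards; many settings leave a gene's region as it was, so the other values say nothing about stability. The null within genes gave 21.8 regions, against 1.08 from shifts. In place of 0 gene lists, 1 passed at a log2 fold of 1, 1 at 2 and 1 over input alone (ribosomal protein genes each time). In Fisher's exact test without matching 1 passed (SR proteins and hnRNPs, adjusted p = 0.0478). The ribosomal ratio in that Fisher's exact test was lower, at 2.42, with an unadjusted p of 0.127. The same 3 ribosomal protein genes held a region, but 1.24 were expected without matching, against 0.429 with matching on called peaks. The core spliceosome ratio was 6.15 with support by all 3 controls (permutation p = 0.00640, adjusted 0.0768). At a −log10 p-value of 8 it was 0, but with 0.361 genes expected no reversal can be read from it. In all, 21 of 192 list results under other settings lay on the other side of the expected number, in 7 lists, 0 of them with an adjusted p under 0.05. Depth is unknown, so its effect on single libraries could not be tested.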

Other observations

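The test on chromosome Y and the genes named here were chosen after their values were seen. Among the 191 regions enriched over the knockout IP and not over input, the strongest was in Rprl3, an RNase P RNA-like gene on chromosome 8 (3803266–3803341, minus strand), with a log2 fold of 7.11 ± 0.38 over the knockout IP and −0.58 ± 0.28 over input (SD, n = 3). The knockout IP itself lay at −2.22 over its input there. Other regions of this set lay above input in all 3 controls but under the threshold. Examples were Srrm2 with 2.25 ± 0.25 and Mink1 with 2.04 ± 0.098 over input (SD, n = 3). Ucp2, a mitochondrial carrier, and Agap1 each held 7 such regions, Vgf held 5 and Nid2 held 4. In Ucp2 the leading region had 5.09 ± 0.32 over the knockout IP and −0.32 ± 0.45 over input (SD, n = 3). The other called peaks of Ucp2 lay 1.69, 2.94 and 2.75 above the list median in controls 1 to 3. Dclk2, Pck2 and the long non-coding gene Gm33272 were the other genes with 2 or more regions whose excess was at least 1 in all 3 controls, and the amino acid transporter gene Slc7a5 had 1.43, 0.79 and 1.17.

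Of these regions, 23 of 191 (12.0%) lay outside protein-coding genes, against 1 of 203 (0.493%) of the regions enriched over both comparators (Fisher's exact test, two-sided, p = 4.46e-07). The regions are not independent, because 11 of them lay on chromosome Y between 90788771 and 90812701. On that chromosome 25 of 32, 17 of 37 and 21 of 30 called peaks of controls 1 to 3 were enriched over the knockout IP, while the knockout had 11 called and 0 enriched peaks over its input. The region in Erdr1, a pseudoautosomal gene on chromosome X (170014175–170014248), had 4.63 ± 1.00 over the knockout IP (SD, n = 3). Pseudoautosomal sequence is shared by chromosomes X and Y. Whether the chromosome Y regions lie in such sequence was not analysed here, so their position alone does not show a Y-linked or sex difference. The strain and sex of the lines are not given in the sources used here. Further regions lay in copies of expressed genes, such as Hmga1b with 4.67 ± 0.24 and Eno1b with 4.39 ± 0.16 over the knockout IP (SD, n = 3).

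A position of the reproducible regions away from gene ends was tested as a hypothesis. Gene strand was taken as the strand with most called peaks, in genes with at least 10, and all 197 regions in such genes lay on that strand. The last 10% of the gene span held 11.2% of them, against 13.9% (9.14% to 18.8% in 95% of draws) for called peaks of the same genes (permutation test with 10000 draws, two-sided, p = 0.294). The bound set beforehand, a missed p, was too weak to exclude a difference, since draws of this number of regions span several percentage points, and the hypothesis stays undecided.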
